A study of Dendroctonus ponderosae with 32 samples.

How the data were processed

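Adult beetles that had emerged from infested pine were stored at 4 °C and treated topically with 10 µg of JH III in 0.5 µL of acetone, or with 0.5 µL of acetone alone, per the labels' protocols. They were then held for 8 h in cups of 10 to 15 beetles of a single sex and treatment. Midgut and fat body were dissected from different beetles, per the labels' protocols, and RNA was sequenced as indexed paired-end libraries. Each index pool held 4 libraries, the 4 sample types of a tissue that carry the same replicate letter, per the labels' protocols. Groups were taken from the labels, and all 32 columns of each table were matched to a sample by its label.

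The authors deposited a table of expected counts, which are estimated read counts per contig, for 15652 transcript contigs in 32 libraries. Its unit was read from the values: 99.3 to 99.7% of the values of a library equalled a whole number exactly, with no tolerance, and totals differed between libraries. FastQC 0.10.1, Trimmomatic 0.30, Salmon 0.6.3, R 3.1.2, edgeR 3.8.5 and limma 3.22.1 are named per the submitters' processing notes, without their roles or order. How the contigs were assembled, and whether strand was used in counting, are not given in the sources used here. The authors also deposited a table of normalized signal for 6889 of the contigs. Each of its 217728 compared values equalled the count divided by a single factor per library within a relative tolerance of 0.001. The contigs in it were those with CPM over 10 in at least 4 libraries, which held for 15652 of 15652 contigs. Normalization factors recomputed with edgeR's TMM on those contigs matched the deposited ones within 1.13e-08%. The count table was used for every test, and the signal table only for this check and for an alternative contig set.

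Total counts of replicates A, B, C and D, in M (1000000 counts), were 4.23, 4.17, 3.70 and 18.9 M in acetone female midgut and 4.71, 6.62, 4.30 and 24.99 M in JH female midgut. They were 6.14, 4.99, 3.76 and 22.7 M in acetone male midgut and 5.54, 4.23, 4.58 and 24.2 M in JH male midgut. Fat body totals were 1.51, 3.72, 6.42 and 22.5 M in acetone females and 1.77, 6.40, 4.05 and 19.8 M in JH females. In males they were 4.92, 6.46, 4.60 and 15.5 M under acetone and 2.29, 5.89, 2.74 and 22.4 M after JH. Between 9373 and 12940 contigs had a count in a library. The 10 most abundant contigs held 9.93 to 18.9% of the counts of a midgut library and 8.80 to 17.0% of those of a fat body library. No replicate pair agreed within counting noise (lowest chi-square per degree of freedom 11.8), so none was merged. Median SEs of a log2 fold change were 0.25 in midgut and 0.31 in fat body for the JH and the sex comparisons.

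Expected counts were rounded to whole numbers first. Contigs with low counts were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and robust quasi-likelihood models were fitted with edgeR 4.0.16 in R 4.3.3. JH, sex and JH by sex comparisons used the 16 libraries of a tissue, and tissue and JH by tissue comparisons all 32. A contig was called at a Benjamini-Hochberg adjusted p under 0.05 within each of the 12 comparisons. Sex differences are male over female and tissue differences midgut over fat body. Fitted fold changes used edgeR's default prior count. A prior count of 2 was used only for log2 CPM, on which list tests, JH scores and correlations of JH effects rest. For a contig with no count in a group, the fold is a lower bound against 3 counts over the group's total, taken from the mean CPM or the pooled rate of the other group, whichever was lower. Fitted values depend on the prior count where a left-out library held all counts of a group. For 1 to 3 counts the ratio of pooled rates is given with its exact 95% interval. Intervals and floors cover counting error only.

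The design, the test, the main alternatives and the rule for naming contigs were chosen before the data were examined. With no product names, the rule took per comparison the 2 contigs with the largest rise and the 2 with the largest fall among those called with non-overlapping groups (not required for interactions) and at least 5 CPM in the higher group. Where the fit without the block called none, the same rule was applied to the fit with it, a choice made after the data were examined. The 25 gene lists fixed beforehand match product names and could not be tested, since 0 contig identifiers matched the 15054 genes of the reference table. No gene name, coordinate or annotation is therefore given.

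The replicate letter marks a shared index pool within a tissue, so it pairs the libraries there. Deviations from group means of libraries with the same letter correlated at a mean r of 0.349 in midgut and 0.409 in fat body, over 24 pairs each. The means for different letters were -0.116 and -0.131, which largely follows from the former values, because deviations from a group mean cancel out within the group. All 16 libraries of each tissue correlated best with their own letter. Across tissues the letters share only a name. The biological coefficient of variation was 27.8% in midgut and 41.2% in fat body, and 19.6% and 26.4% with the pool as a replicate block.

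The fits were tested on simulated counts in which about 100 contigs each were changed 2-fold and 4-fold. The counts were drawn from the fit with the replicate block, so this setting favours that fit over the fit without it. For JH in female midgut, over 7835 contigs, 41.4% of 2-fold and 89% of 4-fold changes were recovered without the block and 66.7% and 97% with it. For JH in male midgut (7824 contigs) the shares were 37.4% and 84% without and 78.8% and 95% with the block. For JH in female fat body (8323 contigs) they were 16.2% and 66.3%, and 51.5% and 80.6%. For JH in male fat body (8332 contigs) they were 17.2% and 67.7%, and 49.5% and 88.9%. Without the block 0 of 130, 0 of 121, 0 of 81 and 1 of 85 calls in these 4 simulations were of unchanged contigs. With it 2 of 165, 10 of 183, 6 of 136 and 12 of 149 calls were.

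Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other size factors, no filter, a stricter filter, a 2-fold minimum, the replicate block, other sets of libraries in the fit and each library left out in turn. Lists of contigs were tested with limma's camera (preset correlation 0.01, and an estimated one) and fry. Correlations of JH effects between comparisons with no library in common were tested over the 70 assignments of 8 libraries, without regard to the index pools. Exact tests of the signal of the other tissue did not use the index pools, because 4 pairs give no two-sided p under 0.125. For each sex, the contigs at least 64-fold higher in a tissue were taken from acetone libraries of the other sex. Those lists therefore differ between the sexes. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.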

Results

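RNA was sequenced from the anterior midgut and the fat body of adult mountain pine beetles (Dendroctonus ponderosae), a bark beetle of pines. Juvenile hormone III (JH), an insect hormone with roles in reproduction and, in bark beetles, in pheromone production, had been applied in acetone to females and males, and control beetles received acetone alone. Tissues were taken 8 h later. The 32 libraries formed 8 groups of 4 (2 tissues, 2 sexes and 2 treatments), with replicates lettered A to D. Total counts, in M (1000000 counts), were 15.5 to 24.99 M in the 8 libraries of replicate D and 1.51 to 6.62 M in the other 24. Values are CPM, counts scaled to 1000000 per library, as mean ± SD with n = 4 libraries per group, and log2 fold changes carry their SE. Transcripts are named by contig, because the files do not pair the contigs with gene names. Counts of a gene may be split among contigs that are fragments, alleles or copies of it. The labels do not say whether the replicates came from separate groups of beetles, so p-values measure only the spread between these samples.

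**Figure D1:**
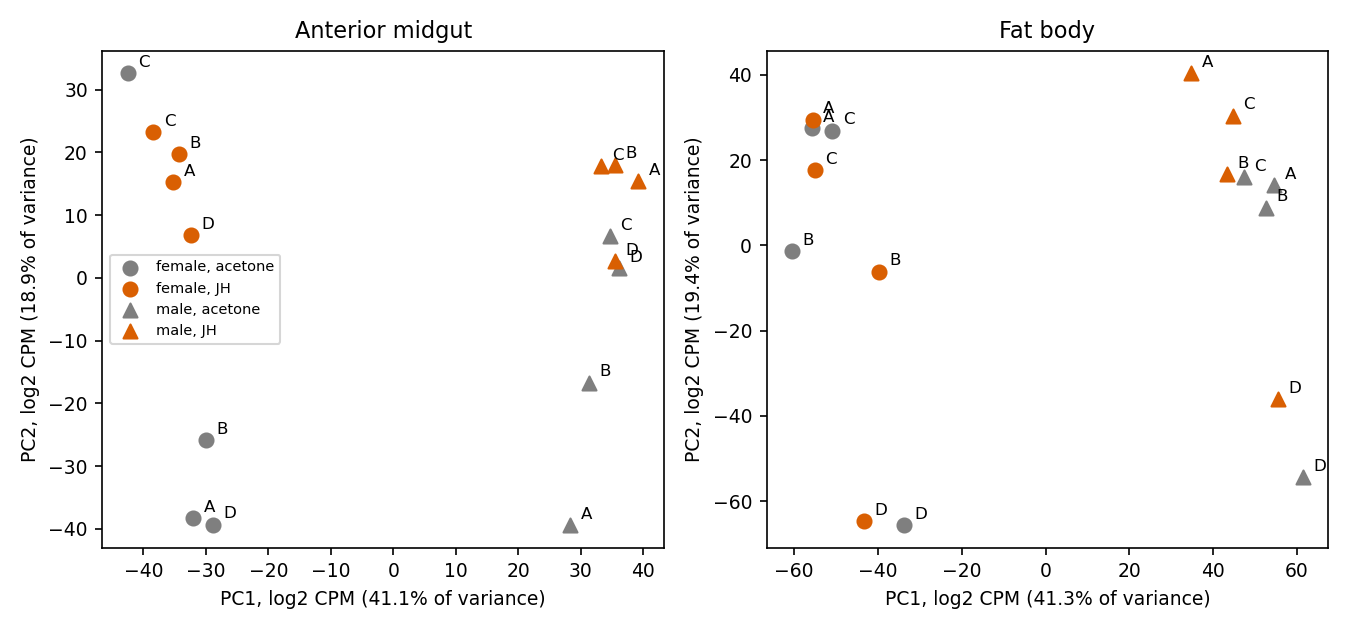
Principal components 1 and 2 of log2 CPM for the 16 midgut libraries (left) and the 16 fat body libraries (right), each point 1 library with its replicate letter, with the percent of variance on each axis. Sexes part on the first component (41.1% and 41.3% of the variance), and acetone female midgut C lies at 32.6 on the second component, where the other acetone female midgut libraries lie between -39.3 and -25.9.

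The treatment comparisons asked which transcripts changed after JH in each sex and tissue. In female anterior midgut, Dpon-CLC-20141217_contig_7015 rose from 50.5 ± 12.8 CPM under acetone to 155 ± 11.8 CPM after JH, a log2 fold change of 1.62 ± 0.27. A smaller rise, from 95.3 ± 13.9 to 173 ± 18.8 CPM, was measured for Dpon-CLC-20141217_contig_1650 (0.86 ± 0.14). Dpon-CLC-20141217_contig_3787 fell from 56.2 ± 27.2 to 17.9 ± 1.63 CPM (-1.65 ± 0.30), and Dpon-CLC-20141217_contig_10241 fell from 64.6 ± 28.1 to 20.9 ± 3.26 CPM (-1.62 ± 0.30). These contigs were among 9 of 7886 that passed edgeR's quasi-likelihood test, 4 higher and 5 lower, each named contig with a Benjamini-Hochberg adjusted p of 0.0439. With the index pool as a replicate block, 760 contigs passed, 412 higher and 348 lower, all 9 among them. The median change of those 760 was 1.61-fold for the higher and 1.67-fold for the lower contigs, and 309 and 255 of them changed less than 2-fold. Acetone replicate C lay with the JH-treated libraries on the second principal component, and without it 794 contigs passed. Contigs at least 64-fold higher in fat body reached 0.872 ± 0.253% of their fat body level in these midgut libraries under acetone and 1.37 ± 0.542% after JH, higher after JH in 3 of 4 index pools (exact permutation test, two-sided, p = 0.171, 0.343 adjusted over 6 such tests). On the scale of all 32 libraries Dpon-CLC-20141217_contig_7015 averaged 1420 ± 927 CPM in acetone and 2499 ± 769 CPM in JH-treated female fat body. The count was 3 without JH replicate D and 0 without any single one of acetone A, B or D or JH A, B or C.

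**Figure D2:**
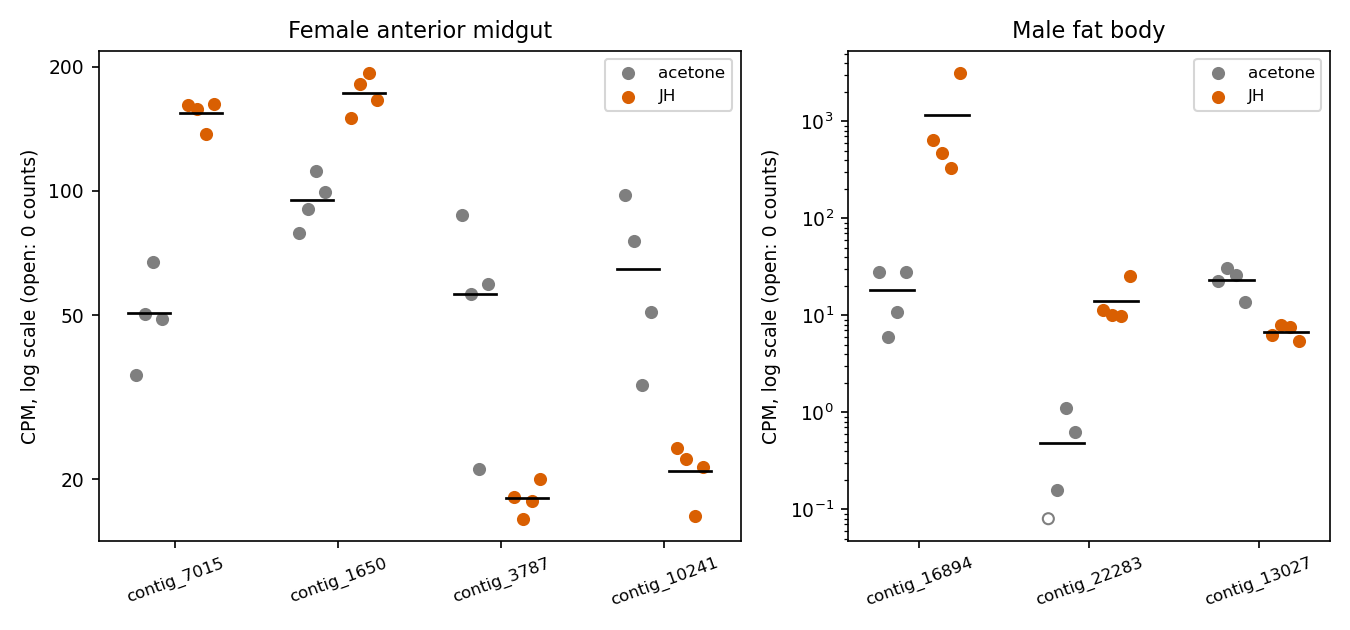
CPM on a log axis of the named contigs in female anterior midgut (left) and male fat body (right), grey for acetone and orange for JH, each point 1 library and each bar the mean of 4 libraries. The open circle is a library with 0 counts, drawn at a fixed low position; Dpon-CLC-20141217_contig_16894 reached 3147 CPM in JH replicate D and 328 to 648 CPM in the other JH libraries.

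In male anterior midgut, no contig passed the same test. The contigs named in females had log2 fold changes of 0.93 ± 0.26 (Dpon-CLC-20141217_contig_7015), 0.32 (Dpon-CLC-20141217_contig_1650), -0.83 (Dpon-CLC-20141217_contig_3787) and -0.98 (Dpon-CLC-20141217_contig_10241) in males. Of the 412 contigs higher after JH in female midgut with the block, 89.8% had a positive change in male midgut (median log2 0.25), and of the 348 lower contigs 4.02% did (median -0.40). These lists were chosen after the data were examined. Over 22 such list tests, limma's camera with a preset correlation gave adjusted p of 1.87e-21 and 1.48e-34, neither of which held with an estimated correlation (adjusted p = 0.293 and 0.235). limma's fry gave adjusted p of 0.30 and 0.0960. By edgeR's quasi-likelihood test 0 of 7886 contigs passed in males, with 595 at an unadjusted p under 0.05 and a smallest Benjamini-Hochberg adjusted p of 0.498. The block gave 0, limma-voom 0 and DESeq2 5. In male midgut the contigs at least 64-fold higher in fat body reached 1.03 ± 0.302% of their fat body level under acetone and 0.986 ± 0.291% after JH, higher after JH in 2 of 4 index pools (exact permutation test, two-sided, p and adjusted p = 0.8286). Without acetone male replicate D, 4 contigs passed.

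**Figure D3:**
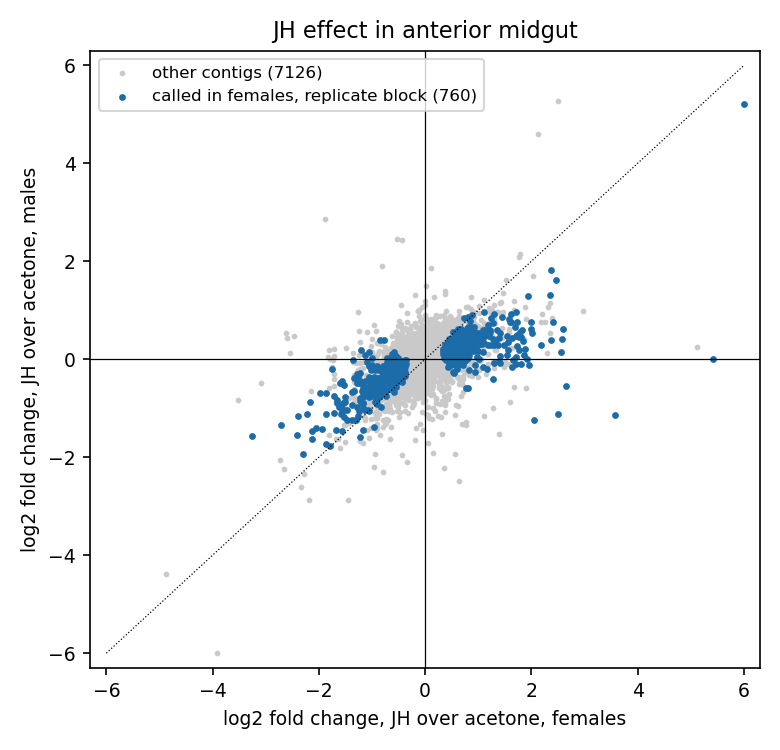
Log2 fold change after JH in female (x axis) and male (y axis) anterior midgut, each point 1 of 7886 contigs, blue for the 760 contigs called in females with the replicate block. 2 contigs beyond 6 on the log2 scale are drawn at the edge. The correlation across contigs, taken from differences of mean log2 CPM, was 0.586.

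Whether the response to JH differed between the sexes was tested as an interaction in each tissue. For no contig did the response differ detectably in midgut, where edgeR's quasi-likelihood test called 0 of 7886, 165 had an unadjusted p under 0.05 and the median SE of a difference was 0.35. DESeq2 called 1 contig, limma-voom 0 and the fit with the block 0. In fat body 0 of 8470 passed, with 144 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom, 0 with the block and a median SE of 0.44. Without acetone female midgut C, 8 contigs passed in midgut.

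In female fat body no contig passed the main test, and contigs are named from the fit with the index pool as a block. In that fit Dpon-CLC-20141217_contig_7040 rose by 2.13 ± 0.35, from 14.8 ± 7.53 to 65.7 ± 21.1 CPM, and Dpon-CLC-20141217_contig_11218 by 2.12 ± 0.32, from 7.12 ± 4.09 to 28.2 ± 9.85 CPM. Dpon-CLC-20141217_contig_9897 fell from 15.0 ± 10.2 to 4.04 ± 1.19 CPM (-1.78 ± 0.36; without the block -1.87, and -1.25 there without acetone D), and Dpon-CLC-20141217_contig_9746 from 115 ± 51.3 to 50.8 ± 7.04 CPM (-1.13 ± 0.23). Their adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0309 for the rising and 0.0466 for the falling pair. That fit called 70 of 8470 contigs, 51 higher and 19 lower, with median changes of 2.60-fold and 2.21-fold. Without the block 0 passed, with 651 at an unadjusted p under 0.05, 88 by DESeq2 and 4 by limma-voom. Contigs at least 64-fold higher in midgut reached 1.40 ± 1.08% of their midgut level after JH and 1.84 ± 0.99% under acetone, and were lower after JH in all 4 index pools (exact permutation test, two-sided, p = 0.629, 0.754 adjusted over 6 such tests). Without acetone female fat body B, 49 passed in the fit without the block.

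In male fat body, Dpon-CLC-20141217_contig_16894 rose from 18.2 ± 11.5 to 1149 ± 1338 CPM after JH, a log2 fold change of 5.97 ± 1.0. Replicate D reached 3147 CPM and the other JH libraries 328 to 648 CPM; without D the change was 4.75. Dpon-CLC-20141217_contig_22283 rose from 0.477 ± 0.504 to 14.2 ± 7.50 CPM (4.85 ± 0.79), on 17 counts under acetone and 642 after JH. Dpon-CLC-20141217_contig_13027 fell from 23.4 ± 7.28 to 6.79 ± 1.12 CPM (-1.78 ± 0.30). They were among 7 of 8470 contigs, 6 higher and 1 lower, that passed edgeR's quasi-likelihood test, each of the 3 at a Benjamini-Hochberg adjusted p of 0.0351. With the block 49 passed, 35 higher and 14 lower, all 7 among them. The count without the block was 1 without acetone replicate D and 0 without any other single library of the comparison, that is acetone A, B or C or JH A, B, C or D. In female fat body Dpon-CLC-20141217_contig_16894 had a change of 0.51 ± 0.85, and the difference between the sexes, 5.47 ± 1.25, had an unadjusted p of 0.000537 and an adjusted p of 0.9999 by the same edgeR quasi-likelihood test. With the block, 6 contigs were higher after JH in the fat body of both sexes (0.211 for independent lists) and 4 were lower (0.0314). These lists were not independent, since the sexes share index pools and the estimates of spread of the same fit. In the fat body libraries, contigs at least 64-fold higher in midgut reached 1.60 ± 0.92% of their midgut level in JH-treated males and 0.756 ± 0.485% in acetone males, higher after JH in 3 of 4 index pools (exact permutation test, two-sided, p = 0.171, 0.343 adjusted over 6 such tests).

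Female and male libraries were compared under acetone to measure the sex difference in each tissue. In anterior midgut Dpon-CLC-20141217_contig_2777 was the most unequal of the female-higher contigs named, at 29916 ± 2745 CPM in females and 149 ± 47.5 CPM in males (log2 male over female -7.65 ± 0.33). Dpon-CLC-20141217_contig_3106 stood at 275 ± 222 CPM in females and 1.48 ± 0.578 CPM in males (-7.60 ± 0.52), and at -6.87 without acetone female C. Dpon-CLC-20141217_contig_39575 had no count in females and 23.7 ± 21.5 CPM in males, at least 245-fold higher against a floor of 3 counts over the group. On the scale of all 32 libraries Dpon-CLC-20141217_contig_39575 averaged 1341 ± 279 CPM in male and 10.1 ± 9.88 CPM in female acetone fat body, and Dpon-CLC-20141217_contig_3106 averaged 5567 ± 2116 CPM in female and 41.4 ± 45.3 CPM in male acetone fat body. Contigs at least 64-fold higher in fat body reached 1.03 ± 0.302% of their fat body level in male and 0.872 ± 0.253% in female acetone midgut, higher in males in all 4 index pools (exact permutation test, two-sided, p = 0.429, 0.643 adjusted over 6 such tests). These were 301 contigs in males and 382 in females, each list taken from acetone libraries of the other sex. The sexes were therefore not compared on the same contigs. Dpon-CLC-20141217_contig_22113 had 1 count in females and 2313 in males, a ratio of 1906 with a 95% counting interval of 342 to 75296. Its fitted log2 difference of 10.69 became 12.30 without acetone female D, which held that count. By edgeR's quasi-likelihood test 430 of 7886 contigs passed, 297 higher and 133 lower in males. Median differences were 4.99-fold and 2.05-fold, and 122 and 18 contigs differed at least 8-fold. Adjusted p (Benjamini-Hochberg, edgeR quasi-likelihood) of the named contigs ran from 2.74e-10 to 0.00370. With the block 822 passed, 469 higher and 353 lower in males, so that the share higher in males was 69.1% without and 57.1% with the block, and 428 of the 430 were among them.

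In fat body Dpon-CLC-20141217_contig_54090 had no count in females and 63.7 ± 40.8 CPM in males, at least 726-fold higher. Dpon-CLC-20141217_contig_33016 had no count in females and 22.2 ± 10.3 CPM in males, at least 253-fold higher. Dpon-CLC-20141217_contig_44823 was lower in males, at 1312 ± 1507 CPM in females and 1.98 ± 0.635 CPM in males (-9.31 ± 0.89, and -8.07 without acetone female D). Dpon-CLC-20141217_contig_20414 also was lower in males (-9.67 ± 1.74), but spread from 1.85 to 2338 CPM among the female libraries and gave -6.67 without acetone female B. edgeR's quasi-likelihood test called 1191 of 8470 contigs, 721 higher and 470 lower in males, with median differences of 4.75-fold and 2.16-fold. The highest adjusted p (Benjamini-Hochberg, edgeR quasi-likelihood) of the named contigs was 0.00124. Midgut-enriched contigs (at least 64-fold) stood at 1.84 ± 0.99% of their midgut level in female and 0.756 ± 0.485% in male acetone fat body, lower in males in all 4 index pools (exact permutation test, two-sided, p = 0.0857, 0.343 adjusted over 6 such tests). These were 358 contigs in females and 158 in males, each list taken from acetone libraries of the other sex. The sexes were therefore not compared on the same contigs. The block gave 2340, 1234 higher and 1106 lower, with 1188 of the 1191 among them. Of 7281 contigs tested in both tissues, 150 were higher in males in both, from 253 in midgut and 452 in fat body, where independent lists of those sizes would share 15.7. Another 44 were higher in females in both, from 122 and 450, against 7.54 for independent lists. Opposite calls were made for 1 and 4 contigs, and the sex differences correlated across contigs at r = 0.701, contigs not being independent replicates. RNA of a tissue carried into dissections of the other would also give shared calls. The overlap cannot tell that from a sex difference in both tissues. On the scale of all 32 libraries Dpon-CLC-20141217_contig_2777 averaged 32622 CPM in midgut and 368 CPM in fat body of acetone females.

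**Figure D4:**
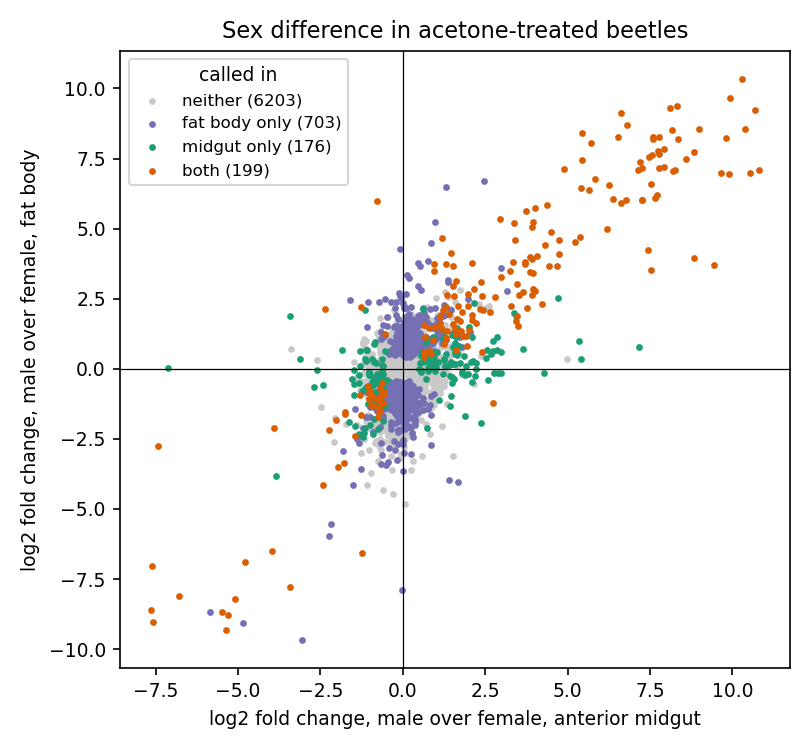
Log2 male over female under acetone in anterior midgut (x axis) and fat body (y axis), each point 1 of 7281 contigs, coloured by the tissue in which it was called. 199 contigs were called in both tissues, 176 in midgut alone, 703 in fat body alone and 6203 in neither; values of contigs with no count in a sex depend on the prior count of the fit.

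Anterior midgut and fat body were compared within each sex under acetone. In females Dpon-CLC-20141217_contig_44 stood at 221 ± 311 CPM in midgut and 0.865 ± 1.18 CPM in fat body (8.81 ± 1.38), and at 7.04 without midgut B, 8.12 without fat body D and 9.54 without fat body A. Dpon-CLC-20141217_contig_54800 stood at 53.5 ± 48.4 and 0.116 ± 0.187 CPM (8.53 ± 1.06), and at 7.62 without midgut B, 7.86 without fat body D and 9.50 without fat body C. Dpon-CLC-20141217_contig_5 had 2 counts in midgut and 196 ± 323 CPM in fat body, a ratio of 1955 (95% counting interval 541 to 16146), with 680 CPM in replicate B and 23.3 to 52.1 CPM in the others. Its fitted difference of -11.30 became -8.88 without fat body B and -13.70 without midgut D, which held both counts. Dpon-CLC-20141217_contig_6028 had no count in midgut and 28.7 ± 19.01 CPM in fat body, at least 160-fold higher, though replicate D held 0.223 CPM. In males Dpon-CLC-20141217_contig_14756 (27.5 ± 3.85 CPM) and Dpon-CLC-20141217_contig_15250 (22.7 ± 2.03 CPM) had no count in fat body and were at least 289-fold and 239-fold higher in midgut. Dpon-CLC-20141217_contig_78967 had no count in male midgut and 23.1 ± 13.2 CPM in fat body, at least 290-fold higher, and Dpon-CLC-20141217_contig_6275 had 1 count in midgut and 32.1 ± 27.2 CPM in fat body, a ratio of 1106 (198 to 43722). The fitted difference of Dpon-CLC-20141217_contig_6275, -9.68, became -8.96 without fat body B and -11.07 without midgut D, which held that count.

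Of 9053 contigs, 4529 passed edgeR's quasi-likelihood test in females (2220 higher in midgut, 2309 higher in fat body) and 5197 in males (2447 and 2750). All 8 contigs named for the tissues passed, with the largest Benjamini-Hochberg adjusted p of that edgeR quasi-likelihood test, 0.0132, for Dpon-CLC-20141217_contig_6028. Median differences in females were 5.70-fold for midgut-higher and 3.73-fold for fat body-higher contigs, and in males 4.08-fold and 4.02-fold. Both sexes shared 1880 midgut-higher and 1895 fat body-higher contigs, where independent lists would share 600 and 701, and 20 and 27 had opposite calls. The sexes were tested in the same fit and share its estimates of spread, so their lists are not fully independent. The tissue differences correlated across contigs at r = 0.898. Each index pool held a single tissue, with 4 pools per tissue, and the tissues came from different beetles.

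Whether the response to JH differed between the tissues was tested in each sex. In females the change after JH in midgut minus that in fat body was 4.54 ± 0.92 for Dpon-CLC-20141217_contig_16884, 3.91 ± 0.88 for Dpon-CLC-20141217_contig_1889, -2.97 ± 0.62 for Dpon-CLC-20141217_contig_3566 and -2.39 ± 0.51 for Dpon-CLC-20141217_contig_3588, in the fit with index pools as a block. Dpon-CLC-20141217_contig_16884 averaged 20.8 ± 5.25 CPM under acetone and 45.2 ± 11.5 CPM after JH in midgut, against 1.94 ± 1.34 and 0.155 ± 0.218 CPM (43 and 3 counts) in fat body. Dpon-CLC-20141217_contig_1889 stood at 11.4 ± 4.87 and 11.7 ± 4.09 CPM in midgut, so its difference came from fat body, at 0.772 ± 0.833 and 0.0787 ± 0.157 CPM (58 and 2 counts). Dpon-CLC-20141217_contig_3566 stood at 7.75 ± 4.38 and 3.63 ± 0.771 CPM in midgut and at 2.36 ± 1.22 and 9.48 ± 5.57 CPM in fat body. Dpon-CLC-20141217_contig_3588 went from 177 ± 24.6 to 130 ± 29.1 CPM in midgut and from 147 ± 105 to 546 ± 169 CPM in fat body. That fit called 40 of 9053 contigs in females, 25 higher and 15 lower, with adjusted p of these 4 from 0.0397 to 0.0480 (edgeR quasi-likelihood, Benjamini-Hochberg). In males it called 1 contig, Dpon-CLC-20141217_contig_843 (-2.61 ± 0.44, adjusted p = 0.0420 by the same edgeR test). It averaged 1086 ± 396 CPM under acetone and 741 ± 240 CPM after JH in midgut, and 8.63 ± 5.14 and 36.2 ± 20.7 CPM in fat body. Contigs at least 64-fold higher in midgut, this contig among them, reached 0.756 ± 0.485% and 1.60 ± 0.92% of their midgut level in the same acetone and JH fat body libraries. Without the block edgeR's quasi-likelihood test called 0 in each sex, with 479 and 359 contigs at an unadjusted p under 0.05, 14 and 2 by DESeq2, and 0 and 0 by limma-voom. In females the count without the block was 16 without acetone midgut C, 11 without acetone fat body B and 1 without acetone fat body D. Leaving out single libraries in that fit gave 3.89 to 6.20 for Dpon-CLC-20141217_contig_16884 and 2.50 to 6.25 for Dpon-CLC-20141217_contig_1889, and -2.94 for Dpon-CLC-20141217_contig_3588 without acetone fat body B.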

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

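The tests of midgut RNA carried over in dissection, and of regrouped libraries and of misassigned reads for the male-limited contigs, were chosen only after the result was seen. In each group of 4 libraries, totals, CPM of named contigs, the signal of the other tissue and a JH score were searched for a library standing far from the rest. Of 55 groups 15 had such a library. Chance gives about 1 in 20 groups for independent, normally distributed values, which these were not. CPM of contigs chosen for large differences made up 35 of the groups and 10 of the 15. Another 5 were the deeper replicate D. The share of groups is therefore no test against chance. The total counts of replicate D stood apart in 5 groups, at 18.9 M in acetone female midgut, 24.99 M in JH female midgut, 22.7 M in acetone male midgut, 24.2 M in JH male midgut and 15.5 M in acetone male fat body. In male fat body after JH, replicate D stood apart at 3147 CPM of Dpon-CLC-20141217_contig_16894 and at 25.4 CPM of Dpon-CLC-20141217_contig_22283. Acetone female midgut C held 606 CPM of Dpon-CLC-20141217_contig_3106 (140 to 197 in the others). For Dpon-CLC-20141217_contig_20414, acetone female fat body B held 2338 CPM (1.85 to 172 in the others) and acetone male fat body C 1.56 CPM (0.576 to 0.634). Acetone female fat body D held 3569 CPM of Dpon-CLC-20141217_contig_44823 (454 to 636 in the others) and 0.223 CPM of Dpon-CLC-20141217_contig_6028 (36.7 to 40.04). Acetone female midgut B held 681 CPM of Dpon-CLC-20141217_contig_44 (17.9 to 131) and 125 CPM of Dpon-CLC-20141217_contig_54800 (20.1 to 35.3). Acetone female fat body B held 680 CPM of Dpon-CLC-20141217_contig_5 (23.3 to 52.1).

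The response to JH differed between the tissues for 40 contigs in females and 1 in males, by the interaction test with index pools as a block. Without the block the same test called 0 in each sex.

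Calls were counted again after the libraries of each comparison had been regrouped. The real split alone of 35 reached 7 calls for JH in male fat body (highest other 4) and 1191 for sex in fat body (highest other 138). For JH in female midgut 2 of 35 splits reached 9 calls. The other split gave 305, several times the real count, which points to a structure of the samples: it placed acetone female C with JH A, B and C. For sex in midgut 2 of 35 splits reached 430, and the highest other, 574, traded acetone female C for acetone male A. Within a tissue the index pools pair the libraries, so only the 8 splits that part every pool are comparable with the real one, too few for a share under 0.05. Among those 8 the highest other gave 0 calls for the 4 JH comparisons and both sex comparisons, and the other splits put libraries of a pool on the same side. For the tissues, whose letters share only a name, chance can be excluded: the real split alone of 35 reached 4529 calls in females (highest other 1018) and 5197 in males (highest other 200). With 0 real calls every split is as large, so the count says nothing about chance for JH in male midgut (35 of 35 splits, highest other 9), JH in female fat body (35 of 35, highest other 58) or the interactions (100 of 100 drawn splits). The highest others of the interactions were 1 and 44 for JH by sex in midgut and fat body, and 368 and 3 for JH by tissue in females and males. The 368 point to a structure of the samples. With the block only 8 swaps within pools exist, too few for a share under 0.05. The real counts were 760, 0, 70 and 49 for JH in female midgut, male midgut, female fat body and male fat body, with highest others of 17, 0, 0 and 0 (1, 8, 1 and 1 swaps as large).

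For 5 of the tests below, the bound written beforehand was set aside after the value was seen. That left the explanation open each time except for misassigned reads among the male-limited contigs. For the treatment label, a score below every JH-treated library had been set to exclude the explanation and was met, but a list from other female libraries placed the library among them. For index pool C, a position over 0.5 had been set to favour it and was met, at 0.556, but acetone male D of another pool lay further, at 0.787. For RNA of another male tissue, a correlation at or below the 95th percentile in both tissues had been set to exclude it and was met. The 94.4 percentile reached lies close to that limit, at a median of 11.5 counts per male library. For misassigned reads in fat body, a share between pools under 50% had been set to exclude them and was met, at 44.8%, but 4 pools give no usable spread for that share. For misassigned reads among the male-limited contigs, the bound concerned only the counts expected in female libraries, at least 3 having been set to favour the explanation, and 17.8 in midgut and 77.1 in fat body were expected. It was worded wrongly, since such reads would put counts there and 0 were found, and the 0 is how those contigs were chosen. Swaps of the sexes within pools were used instead, which ask whether the pattern follows sex, as misassigned reads would not.

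The first pattern is acetone female midgut C, which lay with the JH-treated female libraries. Its JH score used, in each direction, the 200 contigs with the smallest unadjusted p for JH in male midgut with the block. None of them was called. On that score the library lay 0.717 of the way from the other acetone to the JH-treated female libraries (0.825, against -0.08 ± 0.09 and 1.18 ± 0.10). It lay at 0.714 after all midgut libraries were thinned to 3692193 counts, which speaks against library size. On contigs taken from female libraries outside pool C it scored 2.89 and JH female C 2.90, so a wrong treatment label stays open. An effect of index pool C, at 0.556 for the acetone male library of that pool, stays open too, because acetone males A, B and D themselves spread with an SD of 1.13. A biological difference between beetles of this library and the other acetone libraries was not tested.

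The second pattern is 20 contigs counted in all 16 male libraries and in no female library, while 0 contigs showed the reverse. They held 6885 counts in males (median 1.87 CPM), and bounds of their pooled rates against 3 counts over the female libraries were 42.4-fold to 253-fold. Chance can be excluded, since 1 of 100 splits of the libraries, the real one, reached 20 and the highest other 0. Of 100 splits that swapped the sexes within pools 1, the real one, reached 20 and the highest other 0. Each index pool held libraries of both sexes, and misassigned reads would reach them without regard to sex. The swaps therefore argue against such reads as the source of this pattern in the 20 contigs. RNA of another male tissue carried into the dissections could not be told apart from expression in both tissues (94.4 percentile in midgut and 76.9 in fat body). The pattern followed the sex of the libraries, but how sex brought it about was not tested.

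The third pattern is that contigs at least 64-fold higher in midgut were counted in fat body libraries at 0.161 to 2.89% of their midgut level. In the 10 libraries with an excess of at least 0.5% over the lowest library of their group, 20.9 to 85.5% of the contigs had an excess. For those contigs the SD of the log2 excess over the SD of the log2 midgut level had a median of 0.97. That is a ratio of spreads, positive whatever the relation, and not a fitted slope. Among the same contigs the excess followed the midgut level with a median r of 0.862 (0.593 to 0.913). That is consistent with midgut RNA carried over in dissection in 8 of the 10 libraries, but r was 0.593 in JH male A and 0.608 in JH male D, and over all contigs the rank correlation was 0.688 to 0.912 in those 8, 0.568 in JH male A and -0.604 in JH male D. Each index pool held a single tissue, so reads misassigned within a pool would bring no midgut reads into fat body libraries. Reads misassigned between pools could not be excluded. Fat body pools held 44.8% of the variance of the signal between them, a share too few pools to be decisive. Low expression in fat body of the same contigs was not tested.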

How the results depend on the processing

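Settings chosen after the data were examined were the authors' contig set, library weights, replicates A to C alone, the removal of midgut-enriched contigs from fat body, acetone female midgut C left out with the block, and all settings of the correlations. Each JH count moved over 1.5 times in at least 1 setting, and for the moves below the cause was not tested, except that replicates A to C alone use fewer libraries. JH in female midgut (9 calls) gave 3 without a filter, 30 with the stricter filter, 326 by DESeq2, 77 by limma-voom, 760 with the replicate block, 74 in the authors' contig set, 1667 with library weights, 0 with A to C alone and 1672 with the block and without acetone female C. JH in male midgut (0) gave 5 by DESeq2. JH in female fat body (0) gave 88 by DESeq2, 4 by limma-voom, 70 with the replicate block, 34 with library weights and 41 with all 32 libraries. JH in male fat body (7) gave 0 without a filter, 89 by DESeq2, 11 by limma-voom, 49 with the replicate block, 82 with library weights, 3 with A to C alone and 41 with all 32 libraries. JH by sex (0 and 0) gave 1 by DESeq2 in each tissue, and in midgut 5 with library weights and 17 with the block and without acetone female C. JH by tissue in females (0) gave 14 by DESeq2, 40 with the replicate block, 95 with library weights and 146 with the block and without acetone female C; in males (0) it gave 2 by DESeq2, 1 with the replicate block and 1 with library weights. Sex in midgut (430) gave 822 with the replicate block and 889 with the block and without acetone female C, and sex in fat body (1191) gave 2340 with the replicate block and 1916 with library weights. The tissue counts (4529 and 5197) stayed within 1.5 times in all 11 other settings each, with 5094 and 5717 under the replicate block. The block left JH in male midgut and both JH by sex comparisons at 0.

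Leaving out each library in turn gave 0 to 794 for JH in female midgut, 0 to 4 in male midgut, 0 to 49 in female fat body and 0 to 1 in male fat body. The highest values came without acetone female midgut C, acetone male midgut D, acetone female fat body B and acetone male fat body D. The ranges were 0 to 8 for JH by sex in midgut and 0 to 16 for JH by tissue in females, both highest without acetone female midgut C, and 0 to 0 for JH by sex in fat body and JH by tissue in males. Sex gave 337 to 499 in midgut and 955 to 1452 in fat body, and tissue 4290 to 4400 in females and 4923 to 5126 in males. No direction reversed: of 131 values of the 7 contigs named for JH, 67 lost the call and 64 kept it, and of 295 values of the 16 contigs named for sex or tissue 4 lost it. Of 204 values of the 9 contigs named from the block, 35 gained a call. Correlations of JH effects over 22 settings each ranged from 0.421 to 0.641 (both midguts), 0.151 to 0.429 (both fat bodies), 0.199 to 0.400 (female tissues) and 0.220 to 0.406 (male tissues). The prior count of log2 CPM was varied, to a lower and a higher value, only for these correlations. It was not varied for the list tests or the JH scores. The planned gene list tests were not run, since no contig had a name. Fat body libraries A to C held as few as 1.51 M counts, and the biological coefficient of variation was 41.2% in fat body and 27.8% in midgut.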

Other observations

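All tests of this part were chosen only after the data had been seen. Changes after JH correlated across contigs between comparisons that share no library, contigs not being independent replicates. Female and male midgut correlated at r = 0.586 (rho 0.564), and female and male fat body at r = 0.362 (rho 0.359). Within a sex, midgut and fat body correlated at r = 0.363 (rho 0.324) in females and r = 0.362 (rho 0.333) in males. Exact one-sided permutation over 70 assignments gave p of 0.0286, 0.0429, 0.0857 and 0.0143, the last being the smallest it can give. The assignments ignored the index pools, which pair the libraries of a tissue and are shared by its female and male libraries. Adjusted over the 4 relations by Benjamini-Hochberg the exact p were 0.0571, 0.0571, 0.0857 and 0.0571, so none passed.

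Dpon-CLC-20141217_contig_16894, which rose after JH in male fat body, was more abundant in male midgut. On the scale of all 32 libraries it averaged 2849 ± 3121 CPM in male midgut under acetone and 5858 ± 1863 CPM after JH, and 88.2 ± 153 and 452 ± 261 CPM in female midgut. In fat body it averaged 16.2 ± 10.2 and 1047 ± 1258 CPM in males and 12.9 ± 13.9 and 18.1 ± 14.5 CPM in females. Its change after JH did not pass in female midgut (2.32 ± 1.27, adjusted p = 0.396) or male midgut (1.07 ± 1.21, adjusted p = 0.879) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

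The contigs at least 4-fold higher in midgut than in fat body, taken from the libraries of the other sex, had a median log2 change after JH of 0.25 in male fat body, with 65.8% positive, and of -0.29 in female fat body, with 28.7% positive. Neither passed limma's camera with an estimated correlation (adjusted p = 0.528 and 0.589), and the difference between the sexes was not tested for the list. In female fat body camera with the preset correlation gave an adjusted p of 0.00012 and limma's fry 0.530, so the outcome there depended on the test. Few contigs separated the tissues completely: 4 had counts in all 16 midgut libraries and no count in fat body, and 3 had counts in all 16 fat body libraries and no count in midgut. Their pooled rates were low, at 0.305 to 0.785 CPM and 0.664 to 2.92 CPM. Signal of the other tissue was found in every library, and a single count there removes a contig. These numbers therefore do not measure how many transcripts are limited to a tissue.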
